A study of Mus musculus with 2 samples.

How the data were processed

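Droplet-based single-cell 3' RNA libraries of mouse tibialis anterior muscle were used, 1 from uninjured muscle and 1 from muscle 24 hours after an injection of 1.2% barium chloride. Groups were taken from the sample titles. The treatment text of both samples names the injection, so whether the uninjured muscle had any injection is not given in the sources used here. Per the submitters' processing notes, the authors made the matrices with Cell Ranger 2.1.1 against the mm10 build. The deposited values were raw UMI counts per gene and barcode, whole numbers without normalization, and barcodes had already been selected before deposit. The annotation release and the barcode threshold are not given in the sources used here. The uninjured matrix held 5581 barcodes with 22994502 UMIs (lowest 1843, median 3237), and the injured matrix 4489 with 39014762 UMIs (lowest 3333, median 7282). Injured cells thus hold more UMIs each, but the width of an interval follows the UMI total of the class, which was higher in the injured library in 3 of the 5 classes compared and lower for endothelial-like (9275256 uninjured, 3669629 injured) and tenocyte-like cells (2039326 and 1970807). Depth per cell and the higher UMI minimum of the injured library can change shares of small cells.

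Counts of rows that share a gene symbol were added, which gave 28625 symbols. Cells with fewer than 200 detected genes (178 uninjured and 64 injured, 96.6% and 96.0% of whose UMIs were haemoglobin) or over 20% mitochondrial UMIs (18 and 4) were left out. Doublets were scored with Scrublet in scanpy. Its automatic threshold marked 1 barcode in each library, 0.0179% and 0.0223%, and so did not work. As fixed in advance, the barcodes with the highest scores were left out instead, a share of 0.8% per 1000 barcodes, or 249 and 161 barcodes. That share is an assumed rate, and doublets that remain can carry transcripts of another class. For clustering, counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen across both libraries, and 30 principal components and 15 neighbours were used with Leiden resolution 1 and no integration. Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9 were used with random seed 0.

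The 30 clusters were named from marker lists of 16 cell types. A marker counted as present when at least 20% of a cluster's cells had it and its mean was at least 2 times the median over clusters. The class with the highest share of present markers gave the name, unless another class had at least 2 and more markers among the 10 genes with the highest fold. Clusters with fewer than 3 present markers, with at least 2 and more markers of another class among those 10 genes, or with fewer than 50 cells and none of their own there, stayed unnamed. A cluster whose strongest other lineage reached 70% of its own marker share was called mixed. The marker lists were fixed in advance but this rule was not: it was set after seeing the data and rewritten several times. Its last change, from a presence limit of 25% and a stricter treatment of other classes' markers, was made because class shares moved under the other settings, so the steadiness of the shares partly reflects a rule chosen for it. Names in the clustering used for the results were the same under the earlier form. Over the 84 shares from other clusterings, 20 lay outside the interval of the main value with the rule used and 29 with the earlier form, where a class without any named cell counted as outside (1 share and 2 shares). Clusters 19 and 25, called mixed, held 301 uninjured and 21 injured cells, and the unnamed cluster 30 held 27 and 7.

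UMIs were summed over the cells of a class per library and given as CPM with exact Poisson intervals. Shares have exact Clopper-Pearson intervals, and a share of 0 is given with the limit that 3 counts allow. Ratios of injured over uninjured have exact conditional binomial intervals. For ratios of single genes, a count of 0 was raised to 3 counts, and such ratios are stated as bounds. For list medians, 2-fold calls of list members and the ranking of named genes, any lower count under 3 was raised to 3, but never past equal rates. All intervals are at 95% and cover counting error only. No p-value was made from cells. Classes with at least 50 cells in each library were compared, which left 5 classes. No cluster of these had more markers of another class than of its own among its 10 leading genes. A list of genes was summarised by the median log2 ratio of members with at least 20 UMIs, where at least 5 were measured, and by its percentile among 10000 random lists of the same size matched on mean expression. A member was called higher or lower by size alone, at 2-fold. Genes over 10 times higher in another class of the same library are named as such, since free RNA in droplets can place them in any cell. Mixed and unnamed clusters and classes under 50 cells in that library were not checked. Fibre transcripts led the mixed cluster 25, and neutrophil-like cells had no class, so this check could miss transcripts of either.

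Genes named individually were chosen by a fixed rule: among genes with at least 30 UMIs and 100 CPM in the library where they were higher, not mitochondrial, ribosomal protein or gene model names and not over 10 times higher in another class, the 10 with the largest and the 10 with the smallest log2 ratio per class, of which the text gives fewer. Values of some genes are not reported here. Members of the marker and gene lists could be named with their list. The whole library followed the same rule without the condition on other classes. Together 92 distinct genes met the rule, 3 of them on X and 0 on Y. Coordinates are those of the mm10 build, 1-based, from a matching GENCODE annotation in which all 92 were located. The gene lists, markers, filters, named-gene rule and planned settings were fixed before the data were examined. Of 111 medians over 24 lists and 5 classes, the 14 whose changes across settings are given in full were picked after the medians were seen, as were the patterns weighed at the end.

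The calculations were tested on simulated Poisson counts for an injured against uninjured class of 11230 genes. Means came from both libraries together, and totals were a set fraction of each library's total. The intervals rest on the same Poisson counting, so the check covers the calculation and not the spread between cells or animals. Its rates do not carry over to classes with fewer UMIs, such as uninjured monocyte and macrophage-like cells with 576494. Of the simulated 2-fold changes, 98.5% lay within their interval, all had the right direction and 56.7% were called at 2-fold. Of 4-fold changes 95.5% and of 16-fold changes 100% lay within the interval, and all were called. Among unchanged genes 1.63% were called. A simulated list of 4-fold higher genes had a median of 1.93 at the 100 percentile, and a list of unchanged genes one of -0.05 at the 44.8 percentile. Settings tried besides the main ones were other cell filters, doublet treatments, resolutions and numbers of components, each library clustered alone, early response and heat shock genes left out, a class for each cell from its own marker score, thinning to 1000 UMIs, other scalings, other count minimums and lists without members over 10 times higher in another class. A common minimum of 3333 UMIs, list medians after thinning or without doublet removal, and the earlier naming rule were added after seeing the data. Gene values and list medians kept the main clusters and names, except by marker score, without doublet removal and at the common minimum. Other cell filters, resolutions, components, the automatic doublet threshold, separate clustering and left-out early response genes were applied to class shares only.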

Results

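The data were 2 droplet-based single-cell RNA libraries from the tibialis anterior, the muscle along the front of the shin, of C57B/6 mice aged 12 weeks. In 1 library the muscle was uninjured, and in the other it had been collected 24 hours after an intramuscular injection of 1.2% barium chloride, a salt used in mice to make muscle fibres degenerate. The comparison asked how the cells of the muscle and their transcripts differed 1 day after injury. Transcripts were counted as unique molecular identifiers (UMIs). The uninjured library held 5581 barcodes and 22994502 UMIs with a median of 3237 per barcode, and the injured library held 4489 barcodes and 39014762 UMIs with a median of 7282. After filtering, 5139 uninjured and 4260 injured cells remained. The lowest UMI count of a barcode was 1843 in the uninjured and 3333 in the injured library, and 53.9% of the uninjured cells kept lay below 3333. With 1 library per group no difference had a replicate check, no test of the conditions was possible, and every interval given is a 95% interval that covers counting error only.

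Sex-linked transcripts separated the 2 libraries. Xist, the RNA that silences an X chromosome in female cells (ENSMUSG00000086503, mm10 chromosome X, 103460366 to 103483254), had 16575 UMIs in 4391 of 5139 uninjured cells. It had 0 UMIs in 4260 injured cells, which allows a share of up to 0.0704% of cells with a detected UMI, not of cells expressing the gene. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 0 UMIs in the uninjured library, where 0 cells allow a share with a detected UMI of up to 0.0584%, and 4456 UMIs in 2497 of 4260 injured cells. Every difference between the libraries given here was also a difference between libraries with unlike sex-linked transcripts.

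Cells with monocyte and macrophage markers made up 2.70% (2.28 to 3.19) of the uninjured and 64.1% (62.6 to 65.6) of the injured cells. Endothelial-like cells, which line blood vessels, made up 52.3% (50.9 to 53.7) and 10.8% (9.90 to 11.8). Fibro-adipogenic progenitor-like cells, the connective tissue cells between muscle fibres, made up 16.1% (15.1 to 17.1) and 10.2% (9.27 to 11.1). Tenocyte-like cells made up 7.61% (6.90 to 8.37) and 3.59% (3.05 to 4.19). Among cells with at least 3333 UMIs, a limit chosen after seeing the data, the fibro-adipogenic shares were 22.3% and 9.25% and the tenocyte shares 11.1% and 3.69%. The endothelial shares there were 41.6% and 10.8%, a smaller difference than without the limit. The monocyte and macrophage shares were 3.55% and 63.8%. Satellite cell-like cells, named from Pax7, Myf5 and other markers of muscle stem cells, were 250 of 5139 uninjured cells, or 4.86% (4.29 to 5.49), and 0 of 4260 injured cells, which allows a share of up to 0.0704% of cells in such a cluster. With each cell named by its own marker score, 5 injured cells, or 0.117%, were satellite cell-like.

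Among the smaller classes, dendritic-like cells were 1 of the uninjured cells and 251 of the injured cells, the latter 5.89% (5.20 to 6.64). They formed a single cluster of which 99.6% came from the injured library, so that class and library were not separable. Glial-like cells made up 5.04% (4.46 to 5.67) and 1.13% (0.832 to 1.49). Above the same limit of 3333 UMIs, glial-like shares were 1.01% and 1.06%, so the lower share was not seen there. Lymphatic endothelial-like cells numbered 50 and 5, T cell-like cells 30 and 12 and erythroid-like cells 66 and 17. Pericyte and smooth muscle-like cells made up 2.14% (1.76 to 2.57) and 2.84% (2.36 to 3.38), and no direction is given because it turned under 4 of the other settings. Clusters with markers of more than 1 lineage held 5.86% and 0.493% of cells, and an unnamed cluster 0.525% and 0.164%. Of the former, cluster 19 had 9 of 10 pericyte and smooth muscle markers, with 191 uninjured and 15 injured cells. The pericyte and smooth muscle-like share above leaves these cells out. Shares are relative, so a class can have a lower share without fewer cells, and the unequal UMI minimum of the libraries can set part of them.

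**Figure D1:**
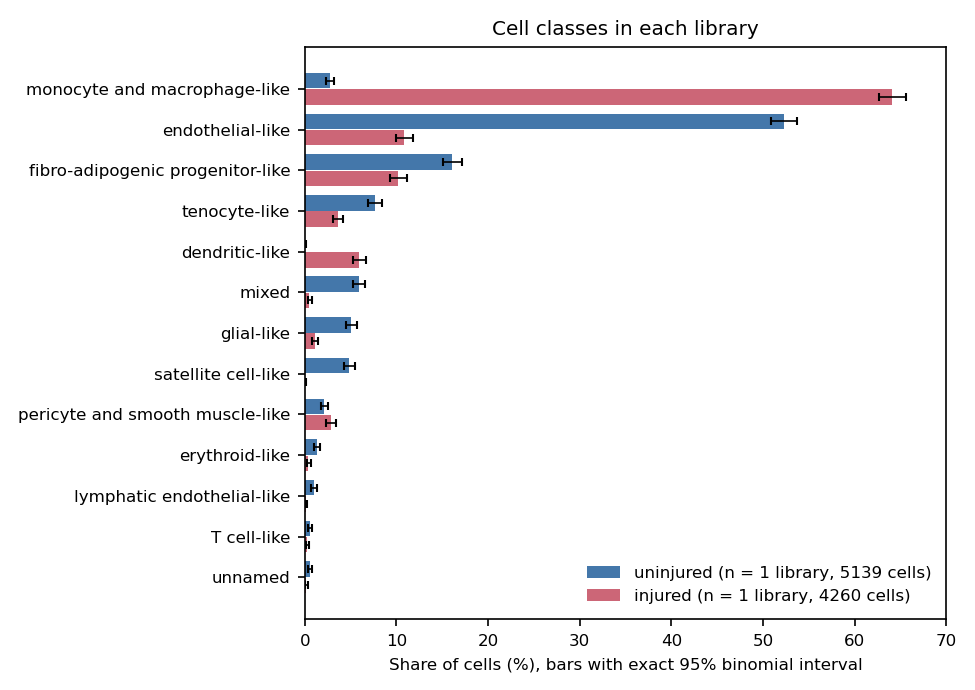
Share of filtered cells (percent, horizontal axis) in each marker-named class for the uninjured (5139 cells) and injured (4260 cells) libraries, with exact Clopper-Pearson 95% intervals that cover counting error only. Monocyte and macrophage-like cells go from 2.70% to 64.1% and endothelial-like cells from 52.3% to 10.8%.

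The monocyte and macrophage-like cells of injured muscle carried less RNA of resident macrophages and of antigen presentation and more of chemokines, cytokines and genes associated with repair. Retnla, a secreted protein of alternatively activated macrophages (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), went from 14847 to 7.67 CPM (UMIs scaled to a fixed total per class and library), 1936-fold lower (1652 to 2285). Arg1, the arginine-degrading enzyme arginase (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), had 0 uninjured UMIs and 825 CPM after injury, at least 158-fold higher. Osteopontin, Spp1, was 137-fold higher (78.6 to 266) at 2858 CPM. The comparison set 139 uninjured against 2731 injured cells, and the 2 libraries lay in different clusters. Of the uninjured cells 120 were in cluster 22, which also held 48 injured cells. The injured cells were mainly in clusters 1, 8, 5, 9 and 18, of which at least 96.3% were injured cells. Retnla, Mgl2, Folr2, Cd163 and Fxyd2 also set cluster 22 apart from the other clusters, and Spp1, Arg1, Il10, Il1rn, Hmox1, Cxcl3 and Ppbp clusters of injured cells.

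All 7 measured MHC class II genes, which present antigen to T cells, were at least 2-fold lower, with a median log2 ratio of injured over uninjured of -3.93. Over all cells of each library the same list had a median of 1.80, with 6 of 7 higher, and H2-Ab1, H2-Aa and Cd74 were among the leading genes of the dendritic-like cluster of the injured library. H2-Ab1 was 15.2-fold lower (14.7 to 15.8), Cd74 10.5-fold lower (10.3 to 10.8) and their activator Ciita 33.3-fold lower (16.8 to 65.8). Of 13 resident macrophage genes 11 were at least 2-fold lower and 0 higher, with a median of -2.51. Over all cells of each library that list had a median of 1.74, with 9 of 14 higher and 3 lower. The genes lower within the class included the hyaluronan receptor Lyve1, 23.5-fold lower (17.6 to 31.2), the haemoglobin scavenger receptor Cd163, 13.9-fold lower (11.0 to 17.6), and Folr2, 8.65-fold lower (7.64 to 9.78). These ratios do not tell a change in each cell from another mix of cells. Cluster 22 held 120 of 139 uninjured but 48 of 2731 injured cells of the class. C1qa, C1qb, C1qc and Mrc1 of that list, and Ccr2, Fcgr1, Ly6c2 and Chil3 of the monocyte list below, also served to name the class. The C-type lectins Mgl2, Cd209d, Cd209f and Cd209g were lower by between 193-fold (151 to 250) for Mgl2 and 535-fold (263 to 1267) for Cd209g, and the sodium pump regulator Fxyd2 was 98.1-fold lower (71.4 to 136). The mast cell proteases Cma1, Tpsb2 and Mcpt4 were also among the lowest ratios, but only 1 uninjured cell held at least 3 UMIs of them.

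Neutrophil-attracting chemokines had a median log2 ratio of 5.13, with 5 of 6 measured members at least 2-fold higher. Cxcl1 was 85.4-fold higher (50.9 to 156) and Ppbp 53.2-fold higher (22.8 to 164). Cxcl3 had 2 uninjured UMIs and was 199-fold higher (55.2 to 1647). Among inflammatory mediators, 8 of 12 were at least 2-fold higher and 0 lower, with a median of 2.98. The prostaglandin synthase Ptgs2 was 14.5-fold higher (9.45 to 23.4), the cytokine oncostatin M, Osm, 8.72-fold (5.99 to 13.2) and the NF-kappaB inhibitor Nfkbia 7.11-fold (6.39 to 7.94). The repair-associated list had a median of 3.99, with 9 of 12 members higher and 1, the growth factor Igf1, 6.66-fold lower (5.38 to 8.19). The interleukin 1 antagonist Il1rn was 21.9-fold higher (11.9 to 45.7) and the fatty acid carrier Fabp5 12.3-fold (9.54 to 16.1). The anti-inflammatory cytokine Il10 had 1 uninjured UMI and was 136-fold higher (24.4 to 5368). Clec4d, a receptor that senses microbes, also had 1 uninjured UMI and was 434-fold higher (77.9 to 17143), and podoplanin, Pdpn, with 2 UMIs was 71.3-fold higher (19.7 to 589). S100a8 had 0 uninjured UMIs and was at least 66.7-fold higher, in a class that included cells grouped as neutrophil-like when the injured library was clustered alone. The 2651 other injured cells of the class had 105 CPM of S100a8, against 347 for the whole class.

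Of 10 inflammatory monocyte genes 7 were higher and 0 lower, with a median of 1.70. The chitinase-like protein Chil3 was 38.9-fold higher (24.3 to 66.7) and versican, Vcan, 28.5-fold higher (11.1 to 105), whereas the chemokine receptor Ccr2 had a log2 ratio of -0.04. Of 14 oxidative phosphorylation genes 0 were at least 2-fold higher or lower, with a median of 0.41 at the 82.0 percentile. Of 14 glycolysis and hypoxia genes 10 were higher with a median of 1.27, among them the pyruvate kinase Pkm, 5.04-fold (4.28 to 5.98), and Pgam1, 4.47-fold (3.42 to 5.98). Of 11 metallothionein, iron and redox genes 9 were higher with a median of 2.05, such as the haem-degrading enzyme Hmox1, 4.14-fold (3.28 to 5.30), while Mt2 was 2.54-fold lower (2.13 to 3.01). Apart from oxidative phosphorylation, every list median given so far for this class lay above or below all of 10000 random lists of the same size matched on mean expression. The interferon-stimulated list had a median of 0.07 at the 78.3 percentile. Of 12 cell cycle genes 6 were lower and 0 higher, with a median of -1.03 at the 6.74 percentile, unlike the higher medians of other classes below. Immediate early genes, which respond to tissue dissociation, had a median of -0.53 at the 0.090 percentile, with 5 of 15 lower and 1 higher. With every cell thinned to 1000 UMIs the repair-associated median was 2.71, and with each cell assigned by its own marker score the resident macrophage median was -3.32. The mediator median was 2.05 when members with as few as 1 UMI were included.

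**Figure D2:**
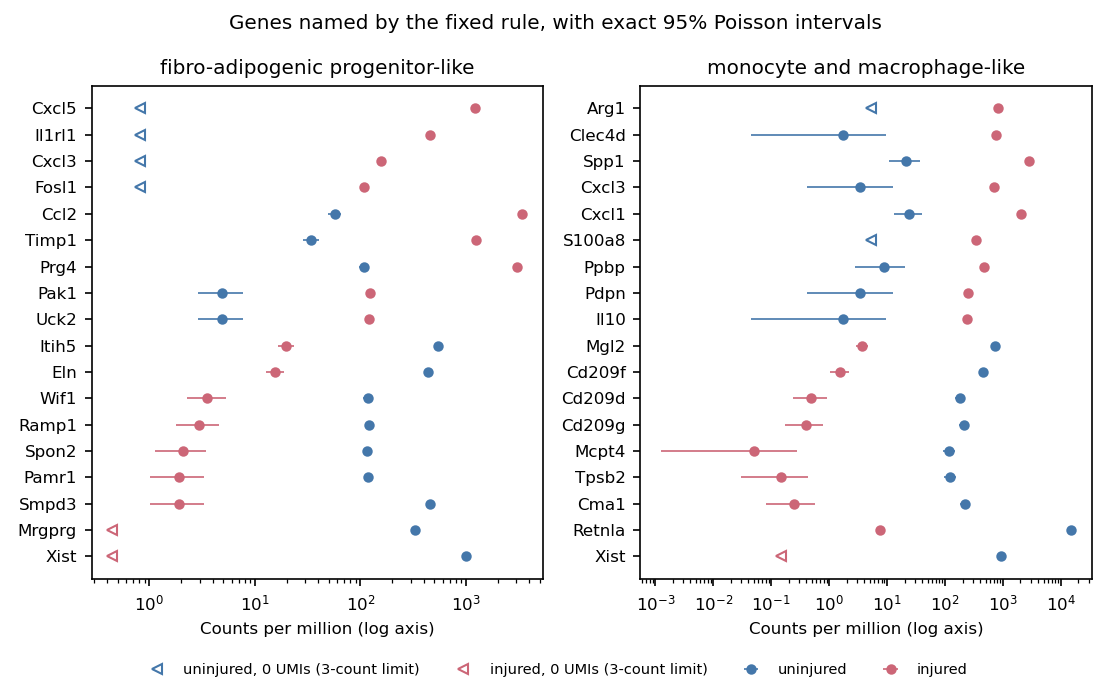
CPM (log horizontal axis) of the 9 genes with the largest and the 9 with the smallest log2 ratio by the fixed rule in fibro-adipogenic progenitor-like and monocyte and macrophage-like cells, for the uninjured and injured libraries, with exact Poisson 95% intervals; open triangles mark 0 UMIs, drawn at the 3-count limit. Cxcl5 goes from 0 to 1223 in the former class and Retnla from 14847 to 7.67 in the latter.

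In fibro-adipogenic progenitor-like cells, genes of the extracellular matrix and of the resting state were lower after injury, and chemokine, proliferation and ribosome assembly genes were higher. Cxcl5, a neutrophil-attracting chemokine (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624), had 0 UMIs in 828 uninjured cells and 1223 CPM in 433 injured cells, at least 1501-fold higher. Ccl2, which attracts monocytes (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), was 60.0-fold higher (52.3 to 69.1) at 3406 CPM. Of 17 fibrillar and basement membrane matrix genes 16 were at least 2-fold lower, with a median log2 ratio of -2.60. Different clusters held the class in the 2 libraries, since 410 of the injured cells were in cluster 7, of which 99.5% were injured cells, and the uninjured cells were in clusters 11, 12, 15 and 27. Cxcl5, Il1rl1, Prg4 and Cxcl14 also set cluster 7 apart from the other clusters, and Mrgprg, Smpd3, Pi16 and C3 cluster 12.

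Elastin, Eln, was 27.8-fold lower (22.8 to 34.2) and the collagens Col15a1, Col3a1 and Col1a1 15.7-fold (12.9 to 19.3), 8.85-fold (8.59 to 9.13) and 8.72-fold lower (8.37 to 9.08). Biglycan, Bgn, was the member within 2-fold. Among 13 homeostasis genes, 12 were lower with a median of -2.42, including the peptidase inhibitor Pi16, 26.6-fold lower (24.1 to 29.5), and Clec3b, 25.8-fold lower (23.4 to 28.4), whereas the chemokine Cxcl14 was 1.80-fold higher (1.74 to 1.86). Dcn, Lum, Col1a1, Col3a1, Gsn, Dpt, Smoc2, Mfap5 and Dpp4 in these lists also served to name the class. Complement genes were lower too: 8 of 10 were at least 2-fold lower with a median of -2.54, such as C3, 10.4-fold lower (9.42 to 11.4). The other 2, C1qb and C1qc, were at least 2-fold higher but were over 10 times higher still in another class. The named lower genes also included the receptor Mrgprg, 330 CPM against 0 UMIs and so at least 746-fold lower, and the sphingomyelinase Smpd3, 237-fold lower (138 to 446). The calcitonin gene-related peptide receptor partner Ramp1 was 40.9-fold lower (26.2 to 67.7) and the Wnt inhibitor Wif1 33.1-fold (22.0 to 52.3). Pamr1, Spon2 and Itih5, all secreted proteins, were lower by between 27.2-fold (22.8 to 32.7) and 61.7-fold (35.7 to 117).

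All 5 measured neutrophil-attracting chemokines were higher, with a median of 5.96, although 2 of the 5 were over 10 times higher in another class, and the median of the other 3 was 7.60. Cxcl3 had 0 uninjured UMIs and was at least 194-fold higher, and Cxcl1 was 8.75-fold higher (8.18 to 9.37). Of 9 monocyte-attracting chemokines 8 were higher with a median of 4.01, although 6 of the 9 were over 10 times higher in another class. The 3 others were Ccl2, Ccl7, 19.1-fold higher (17.1 to 21.3), and the macrophage growth factor Csf1, 3.49-fold higher (3.14 to 3.90). Il1rl1, the receptor for interleukin 33, had 0 uninjured UMIs and was at least 562-fold higher, and the AP-1 subunit Fosl1 likewise was at least 132-fold higher. Lubricin, Prg4, was 28.3-fold higher (25.7 to 31.4) at 3042 CPM, the kinase Pak1 25.1-fold (15.8 to 42.5) and the nucleoside kinase Uck2 24.6-fold (15.5 to 41.8). Of 17 matrix remodelling genes 8 were higher and 3 lower, with a median of 0.82. The metalloproteinase inhibitor Timp1 was 36.4-fold higher (30.6 to 43.8) and the urokinase receptor Plaur 19.2-fold higher (12.6 to 30.9), while fibronectin, Fn1, was 9.10-fold lower (8.64 to 9.60).

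Cell cycle genes had a median log2 ratio of 3.47 in these cells, with 15 of 16 members at least 2-fold higher. The DNA replication licensing genes Mcm5 and Mcm6 were 39.3-fold (18.9 to 98.2) and 10.5-fold higher (7.56 to 14.9). All 14 ribosome biogenesis genes were higher with a median of 2.51, among them nucleolin, Ncl, 7.72-fold (7.12 to 8.38), and Npm1, 7.32-fold (6.90 to 7.77). Of 12 inflammatory mediators 9 were higher with a median of 2.10, including the prostaglandin synthase Ptgs2, 5.44-fold (4.44 to 6.72), and Il6, 3.40-fold (2.68 to 4.35). Of 12 interferon-stimulated genes 10 were lower and 0 higher, with a median of -1.93 at the 0.020 percentile. The cell cycle median was 2.16 without doublet removal, the mediator median 1.20 without members over 10 times higher in another class and the homeostasis median -1.75 as a mean of per-cell normalised values. Immediate early genes, which respond to tissue dissociation, had a median of -1.23, with 8 of 15 lower and 1 higher. Heat shock genes had a median of 1.23, with 6 of 11 higher and 3 lower. Transcripts of muscle fibres, which these cells are not known to make, were lower in all 8 measured members with a median of -3.24.

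In endothelial-like cells, genes of capillaries and of the interferon response were lower after injury, and genes of ribosome assembly and matrix remodelling were higher. Placental growth factor, Pgf (ENSMUSG00000004791, chromosome 12, 85166635 to 85177790), was 164-fold higher (122 to 227), and the peptide ligand Apln (ENSMUSG00000037010, chromosome X, 48025146 to 48034853) 56.9-fold higher (47.2 to 69.1). The metalloproteinase inhibitor Timp4 (ENSMUSG00000030317, chromosome 6, 115241892 to 115252205) was 17.8-fold lower (15.2 to 20.9). The comparison set 2687 uninjured against 461 injured cells. Uninjured cells were mainly in clusters 2, 3, 4 and 6, whereas 348 injured cells were in cluster 10, of which 97.8% were injured cells. Pgf, Apln, AA467197, Sh2d5, Bmp2 and Angpt2 also set cluster 10 apart from the other clusters, Timp4 clusters 2 and 3, Hspa1a cluster 2, Aqp1 and Sult1a1 cluster 3 and Vwf cluster 6.

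Of 10 capillary genes 9 were at least 2-fold lower, with a median log2 ratio of -2.31. They included the fatty acid transporter Cd36, 6.61-fold lower (6.20 to 7.06), the lipoprotein lipase Lpl, 5.26-fold (4.69 to 5.91), and the water channel Aqp1, 4.69-fold (4.55 to 4.83). Of 14 interferon-stimulated genes 13 were lower, with a median of -2.22. The antiviral genes Ifit2 and Rsad2 were 15.3-fold (7.68 to 35.8) and 11.6-fold lower (8.92 to 15.5), and the regulator Irf7 7.04-fold (5.54 to 9.07). Among single genes with the lowest ratios, Cyp26b1, which degrades retinoic acid, was 39.0-fold lower (23.2 to 71.5), the retinol-binding protein Rbp7 15.2-fold (12.7 to 18.4) and the retinaldehyde reductase Dhrs3 12.4-fold (10.2 to 15.3). Sult1a1, Thrsp and Tmem140 were lower by 14.8-fold (12.1 to 18.4), 12.3-fold (9.66 to 15.9) and 11.9-fold (9.47 to 15.2). The heat shock genes Hspa1b and Hspa1a were 16.4-fold (11.5 to 24.3) and 11.8-fold lower (10.6 to 13.2), although the heat shock list of 11 had 3 higher and 3 lower members. The immediate early list had a median of -0.91, with 7 of 15 lower and 0 higher.

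Of 14 ribosome biogenesis genes 13 were higher with a median of 1.79, such as Rrp12, 11.5-fold (5.51 to 26.9), and nucleostemin, Gnl3, 6.97-fold (5.84 to 8.36). Of 13 matrix remodelling genes 9 were higher with a median of 3.07. Tenascin C, Tnc, was 38.1-fold higher (21.8 to 72.9) and the membrane metalloproteinase Mmp14 13.8-fold (11.1 to 17.1). Cell cycle genes had a median of 1.42 with 8 of 13 higher. Of 12 endothelial activation genes 5 were higher and 3 lower: angiopoietin 2, Angpt2, was 4.37-fold higher (3.87 to 4.93) and E-selectin, Sele, 2.36-fold higher (1.62 to 3.44), whereas von Willebrand factor, Vwf, was 3.27-fold lower (2.91 to 3.69). Further genes with high ratios were the transcriptional regulator Ankrd1, 149 CPM against 0 UMIs and at least 460.0-fold higher, AA467197, 387-fold higher (265 to 588), the morphogen Bmp2, 75.5-fold (47.3 to 128), and the tubulin Tubb6, 33.7-fold (29.4 to 38.7). The neuropeptide precursor Gal had 2 uninjured UMIs and was 627-fold higher (173 to 5190.4), and Sh2d5 had 1 and was 981-fold higher (175 to 38834). S100a8 and S100a9 had 1 and 3 uninjured UMIs and were 1835-fold (328 to 72578) and 325-fold higher (110.5 to 1584), but 57.2% of all injured S100a8 UMIs lay in 82 neutrophil-like cells. Those 82 cells, found with the injured library clustered alone, had 8286 CPM of S100a8 and 3940 of S100a9. The other injured endothelial-like cells had 174 and 91.9 CPM. Both genes were thus over 10 times higher in neutrophil-like cells, which formed no class that the naming rule could check. The matrix remodelling median was 2.25 after thinning to 1000 UMIs and 4.02 without members over 10 times higher in another class. Fibre transcripts were lower in all 10 members with a median of -2.05.

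Tenocyte-like cells, the fibroblasts of tendon, had lower fibrillar matrix genes and higher redox and cell cycle genes in the injured library. Of 17 matrix genes 11 were lower and 1, lumican, 2.08-fold higher (1.85 to 2.34), with a median log2 ratio of -1.81. Col1a1 was 9.50-fold lower (9.20 to 9.81) and Col1a2 8.56-fold (8.33 to 8.80). The muscle-tendon junction collagen Col22a1 was 62.9-fold lower (36.6 to 119), and the lectin Reg3g had 0 injured UMIs and was at least 192-fold lower. The acute phase genes Saa3 and Lcn2 were at least 136-fold and 93.1-fold (44.9 to 233) higher, and the protease inhibitor Serpina3n was 28.9-fold higher (18.1 to 49.1). Il1rl1 and the metalloproteinase Mmp3 each had 1 uninjured UMI and were 1407-fold (252 to 55625) and 1103-fold higher (198 to 43609). Of 11 metallothionein, iron and redox genes 8 were higher with a median of 1.92, such as Mt2, 9.17-fold (8.58 to 9.82), and Hmox1, 7.90-fold (4.88 to 13.5). Of 9 cell cycle genes 7 were higher with a median of 2.46. The uninjured 391 cells were in clusters 17 and 21, and 152 of 153 injured cells in cluster 23, of which 100% were injured cells, so that cluster and library were not separable. Il1rl1, Mt2 and Serpina3n also set cluster 23 apart from the other clusters, Col1a1 and Col1a2 cluster 17 and Col22a1 cluster 21.

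Pericyte and smooth muscle-like cells lay in cluster 16 in both libraries, with 110 and 121 cells. Cluster 19 had the pericyte markers Kcnj8, Rgs5 and Abcc9 among its leading genes and held 191 uninjured and 15 injured cells. It was called mixed, since endothelial markers were present too, and is not covered by the values here. The makeup of cluster 16 differed between the libraries. The smooth muscle markers Myh11, Tagln and Acta2 were 14.3-fold (12.1 to 16.9), 7.33-fold (6.85 to 7.86) and 6.89-fold lower (6.58 to 7.22), and the endothelial markers Cldn5, Pecam1 and Cdh5 were 7.11-fold (4.99 to 10.5), 4.89-fold (3.36 to 7.39) and 4.59-fold higher (3.33 to 6.49). Under 3 other settings only 8, 10 or 38 injured cells had this name, so the following values describe the cluster and not a given cell type. Ccl2 was 108-fold higher (42.0 to 396) in the injured cells and the protease inhibitor Ctla2a 19.2-fold higher (11.4 to 35.2). Of 12 ribosome biogenesis genes 11 were higher with a median of 1.56, and all 7 inflammatory mediators were higher with a median of 2.17, of which 3 were over 10 times higher in another class. Fibre transcripts were lower in all 7 members with a median of -3.53, and 1 of them, Pvalb, was among the genes with the lowest ratios at 33.8-fold lower (15.6 to 86.9). Pvalb also led the mixed cluster 25, which had 9 of 10 skeletal muscle fibre markers and was left out of the check against other classes. Across all filtered cells, fibre transcripts had a median of -2.37 with all 10 lower, and in monocyte and macrophage-like and tenocyte-like cells of -1.90 and -2.40.

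**Figure D3:**
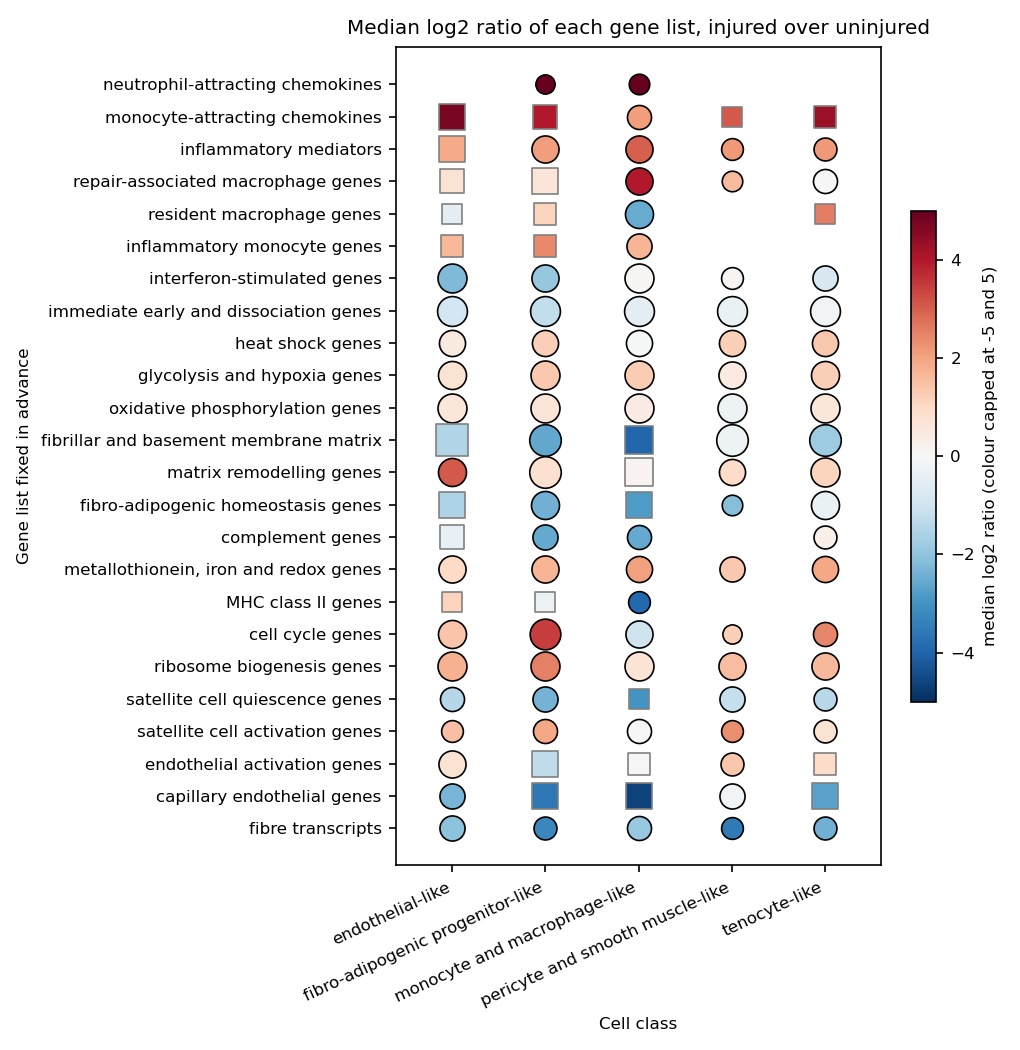
Median log2 ratio of injured over uninjured (colour, capped at -5 and 5) of each gene list (rows of the plot) in the 5 cell classes compared (horizontal axis); symbol size grows with the number of measured members. Squares with a grey edge mark lists with most members over 10 times higher in another class, and fibre transcripts are below 0 in all 5 classes. Mixed clusters were not among the classes checked. Fibre transcripts, which led the mixed cluster 25, are thus drawn as circles without a check against that cluster.

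Over all cells of each library together, as a bulk sample would show, the values reflected makeup and expression at once. Cxcl2 went from 26.8 to 10228 CPM, 382-fold higher (351 to 416), the lectin Clec4e was 473-fold higher (306 to 775) and Chil3 769-fold higher (480.0 to 1319.8). Chodl, found mainly in uninjured tenocyte-like and satellite cell-like cells, was 48.5-fold lower (39.2 to 60.8), the lectin Lgals7 305-fold lower (178 to 574), the glycerol channel Aqp7 45.0-fold lower (37.9 to 53.9) and the adipokine-like C1qtnf9 38.5-fold lower (35.3 to 42.1). Of 14 satellite cell quiescence genes 13 were lower with a median log2 ratio of -3.08. That list was not particular to satellite cell-like cells. Its median was between -1.21 and -3.00 in each of the 5 classes compared, and Hey1 was a leading gene of the endothelial-like cluster 4. Pax7 had 377 uninjured and 6 injured UMIs, and Myod1, a regulator of muscle stem cell activation, had 214 UMIs in 98 uninjured cells and 202 UMIs in 16 injured cells. Of 12 satellite cell activation genes 4 were higher and 3 lower. Under median ratio scaling the median of all genes shifted by 0.47 on the log2 scale for whole libraries, which is smaller than the list medians given here.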

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

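The tests of the sex-linked transcripts and of the satellite cells were chosen only after the results were seen. The interferon tests were written down before their values were known but after the list median had been seen, and all 3 patterns were picked after seeing the data.

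Signal appeared in genes that no comparison used: 4 Y-linked genes, Ddx3y, Eif2s3y, Kdm5d and Uty, had 4456 UMIs in the injured and 0 in the uninjured library, and Xist had the reverse. At the injured library's rate, 2489 Y-linked UMIs would be expected in the uninjured library, which argues against its lower depth. The 4456 Y-linked UMIs argue against a loss of Xist after injury in animals of the same sex, since such cells would have none. The number of cells with the other library's sex-linked transcripts, 0, only restates this pattern. Xist UMIs lay in 4391 of 5139 uninjured cells and Y-linked UMIs in 2497 of 4260 injured cells. With 0 in the other library, these counts argue against animals of the same sex in both libraries. Sex itself is not given in the sources used here. With 1 library per group, a difference of sex cannot be told apart from injury in any comparison.

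No satellite cell-like class was found in the injured library. If infiltrating immune cells had only diluted it, its share among non-immune cells, here also without erythroid-like cells, would be alike in both libraries. That share was 5.10% (4.50 to 5.75) in uninjured muscle, against at most 0.240% allowed by 0 of 1249 injured cells. Among uninjured non-immune cells with at least 3333 UMIs it was 5.45% with a lower limit of 4.54%, which argues against the unequal UMI minimum. Satellite cells whose markers changed, and which were named otherwise, cannot be told apart from missing cells: 16 injured cells had a UMI of Myod1, Myf5 or Pax7, against 63.7 satellite cells expected, while 26 uninjured cells outside the satellite class also had such a UMI, so a UMI alone does not identify these cells. Of the injured cells, 16 held 202 Myod1 UMIs, against 214 in 98 uninjured cells, and 7 had UMIs of at least 2 of these genes, against 156 uninjured cells. In the fibro-adipogenic class lay 10 of the 16 injured cells with Myod1, all 4 with Pax7 and all 5 with Myf5. Some satellite cells may thus have been named otherwise, which these counts do not decide. Injury, sex, death or poor release of the cells during tissue digestion stay open and were not tested.

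Interferon-stimulated genes had a median log2 ratio of -2.22 in endothelial-like cells. Without the 20% of uninjured cells highest in the list, 537 cells with 49.1% of its UMIs, the median was -1.45, so these cells did not make the whole difference. With every cell thinned to 1000 UMIs it was -2.16. The ratio was already taken over class totals and so scaled for depth before thinning, and the thinned value does not decide on depth. Thinning can move such medians: matrix remodelling in these cells went from 3.07 over 13 members to 2.25 over 11. Against each uninjured endothelial-like cluster of 50 or more cells in turn, clusters 2, 3, 4 and 6, the highest median was -1.37. This argues against another mix of those clusters as the whole source. Cluster 10 held 348 injured but only 8 uninjured cells and was left out, so a shift towards its state was not tested. A lower interferon tone after injury, a difference of sex and any other difference between the animals, such as exposure to infection, stay open and were not tested.

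Repair-associated macrophage genes had medians of opposite sign in different classes when members over 10 times higher in another class were left out. The median log2 ratio was 3.99 over 12 members in monocyte and macrophage-like cells, -2.19 over 5 members in fibro-adipogenic progenitor-like and -1.04 over 5 members in tenocyte-like cells, with 3 of the 5 at least 2-fold lower in each. Over all measured members the latter 2 medians were 0.65 (11 members) and 0.03 (9 members), so the opposite direction rests on leaving members out. The difference between classes was not tested.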

How the results depend on the processing

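The common minimum of 3333 UMIs, the earlier naming rule, and the list medians after thinning or without doublet removal were chosen after seeing the data. Of 97 other values of 7 class shares, 74 stayed within the counting interval of the difference, 18 moved outside it with the same direction and 5 reversed. Those that stayed include the earlier naming rule on the main clustering, which gave the main shares for all 7 classes and so could not differ. The automatic doublet threshold marked 1 barcode per library, so it nearly repeats the setting without doublet removal. Of 140 other values of the 14 list medians followed here, 96 stayed within the interval from Poisson resampling and 44 moved, none with a change of direction. List medians and named genes were not recomputed under other cell filters, resolutions or components, with libraries clustered alone or without early response genes. Their counts thus do not cover those choices. For the other list medians 809 of 1109 values stayed and 300 moved (a median under 1 in size counted as moved even where its sign changed), and for named genes 651 of 831 stayed and 180 moved. The causes were not tested. The steadiness of the shares partly reflects a naming rule chosen for it: with the earlier form, injured monocyte and macrophage-like cells were 1774, or 41.6%, at the common UMI minimum, and after thinning injured fibro-adipogenic progenitor-like cells were 14 and uninjured satellite cell-like cells 0. On the clustering used for the results it gave the same shares. No paired analysis was possible because the groups share only replicate number 1 and no result comes from a test.

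Differences in share, injured minus uninjured, are in percentage points. For monocyte and macrophage-like cells, 61.4 in the results, the difference was 66.3 without a cell filter, 66.2 with the automatic doublet threshold, 54.2 at resolution 2, 67.2 without early response and heat shock genes, 66.9 after thinning and 53.5 by marker score. For endothelial-like cells, -41.5, it was -39.3 with the automatic threshold, -39.0 at resolution 2 and without doublet removal, -38.9 by marker score and -30.9 with the common UMI minimum. For fibro-adipogenic progenitor-like cells, -5.95, it was -4.27 after thinning and -13.1 with the common minimum, and for tenocyte-like cells, -4.02, it was -5.09, -7.42 and, with 15 components, -5.31. For satellite cell-like cells, -4.86, it was -3.93 by marker score. For glial-like cells, -3.91, it was 0.0428 with the common minimum, a reversal. For pericyte and smooth muscle-like cells, positive in the results, it reversed to -1.17 without early response genes, -2.65 by marker score, -1.23 with 15 components and -0.614 at 10% mitochondrial UMIs, and was 2.51 with each library clustered alone. Resolution 0.5 gave no value there, since the cells lay in a mixed cluster.

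After thinning, endothelial medians were 2.25 for matrix remodelling, 1.95 for ribosome biogenesis and -2.15 for capillary genes. Those of fibro-adipogenic cells were 1.46 for mediators, -2.21 for matrix and -1.93 for homeostasis, and those of monocytes and macrophages 2.71 for repair, -2.78 for resident and -3.56 for MHC class II genes. The tenocyte matrix median was -1.51. By marker score, fibro-adipogenic matrix, homeostasis and cell cycle medians were -2.41, -2.18 and 4.09, and macrophage mediator, resident and MHC class II medians 2.61, -3.32 and -3.73. Without doublet removal, capillary, homeostasis, cell cycle and MHC class II medians were -2.23, -2.26, 2.16 and -3.42, and with the common UMI minimum -2.06, -2.21, 2.48 and -4.01. Without members over 10 times higher in another class, endothelial matrix remodelling was 4.02 and fibro-adipogenic mediators 1.20. With totals without mitochondrial, ribosomal protein and haemoglobin genes, endothelial ribosome biogenesis and capillary medians were 1.90 and -2.19, fibro-adipogenic mediator, matrix, homeostasis and cell cycle medians 2.36, -2.34, -2.16 and 3.73, the MHC class II median -4.02 and the tenocyte redox median 2.15. As means of per-cell values, capillary, fibro-adipogenic matrix, homeostasis, resident and MHC class II medians were -2.15, -2.22, -1.75, -2.68 and -3.83. With at least 50 UMIs per member, fibro-adipogenic mediators were 1.65 and MHC class II -3.66, and with at least 1 UMI the mediators of the 2 classes were 1.65 and 2.05. Homeostasis was -2.27 under median ratio scaling.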

Other observations

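The classes of injured muscle differed in the signals they carried. Fibro-adipogenic progenitor-like cells, 10.2% of injured cells, held 96.0% (95.6 to 96.4) of the UMIs of the neutrophil-attracting chemokine Cxcl5, 81.0% (79.6 to 82.4) of the macrophage growth factor Csf1 and 78.0% (74.6 to 81.1) of the alarmin Il33. Monocyte and macrophage-like cells held 96.9% (96.8 to 96.9) of Cxcl2 and 83.0% (82.9 to 83.2) of Ccl2. They also held 94.5% (94.1 to 94.9) of Tnf and 96.2% (95.8 to 96.6) of Osm. The monocyte and macrophage-like class included cells grouped as neutrophil-like under other settings, whose part in these shares was not separated. Cxcl1 was shared, with 71.7% in monocyte and macrophage-like and 24.6% in fibro-adipogenic progenitor-like cells. Il6 was spread further, with 51.5% in the former, 24.0% in the latter and 10.8% in endothelial-like cells. Endothelial-like cells held 76.0% (70.2 to 81.1) of 254 UMIs of the nitric oxide synthase Nos2. These genes were members of the fixed lists, singled out after their values were seen, and the shares also reflect the number and depth of cells per class.

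Neutrophil-like cells formed no cluster of their own when both libraries were clustered together at resolution 1. Clustered alone, the injured library gave a cluster of 82 cells, 1.92% (1.53 to 2.38), with 9 of 10 neutrophil markers, and 63 of them lay in cluster 1 of that joint clustering. The marker score per cell named 197 injured and 0 uninjured cells, and joint clustering at resolution 2 gave a neutrophil-like cluster of 345. S100a8 UMIs per S100a9 UMI were 2.10 in the 82 cells, 4.04 in the other monocyte and macrophage-like cells, 1.89 in endothelial-like and 1.86 in fibro-adipogenic progenitor-like cells.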
